A study of Oryza sativa with 6 samples.

How the data were processed

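Sequencing libraries were made with the Hieff NGS Ultima Dual-mode mRNA kit, per the labels' protocols, from Trizol-extracted root RNA of 3 WT and 3 mads61-3 samples. The labels give the groups and the replicate numbers, and the growth protocol, which also mentions overexpressing plants, gives 2.5 mM nitrate for both groups. Nothing in the labels says that replicates came from separate tanks or plants, so p-values measure only the spread between these samples, which may be technical. The deposited columns named mads61 with a number 1 to 3 were read as replicates 1 to 3 of line mads61-3.

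The deposited table of read counts holds whole-number counts per feature that were not normalised, with 36960 features. Of these 35254 are rice RAP loci, 1600 are assembled features with MSTRG names and 106 are organelle genes, and 9346 carry a gene name. The deposited FPKM table holds fragment values scaled by the authors to feature length and library depth, for the same features and libraries. Per the submitters' processing notes, CASAVA 1.8.2, FastQC 0.11.9, HISAT2 2.0.5, StringTie 1.3.3, Picard 1.41 and SAMtools 0.1.18 were used. The genome build named there is GRCh38, a human build, although the identifiers are rice loci. The rice build, the annotation, the read counter and its use of strand are not given in the sources used here, so no coordinates are given. The chromosome is the one in the locus identifier, and reads of antisense or overlapping genes cannot be told apart. Of the deposited identifiers 1 was found in the RefSeq gene table of assembly ASM3414082v1, so gene names were taken from the deposited table alone. All 12 value columns of the 2 tables were used. Log2 FPKM and log2 CPM were compared across 22882 genes with a mean of at least 1 CPM. Taken as deviations from each gene's mean over the libraries, they correlated at r = 0.983 to 0.989 for the same library. Those of differently named columns correlated at 0.725 or less. Without this centring, Spearman's rho for the same library was 0.932 to 0.947. Genes are not independent replicates in such a correlation.

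Library totals ran from 24145708 to 34179150 counts. A count of 0 was given the upper limit of 3 counts per library, and ratios of genes with 1 to 3 counts in a group have exact 95% intervals. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

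The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, on the counts as deposited, two-sided, with TMM scaling, robust estimation, the default filter on low counts (minimum count 10, minimum total 15), the group as the only term, and Benjamini-Hochberg adjustment over the 25531 features kept. A gene was called at an adjusted p under 0.05, and adjusted p-values in the text come from this test unless another is named. Standard errors of log2 fold changes (mutant over WT) were computed as the size of the fold change divided by the square root of F. Values in CPM are counts scaled by TMM library sizes. An exact test of a single value between 3 and 3 libraries cannot give a p below 0.1. Averaged over the splits, chance puts all libraries of one group on one side of the other in 10% of genes. On simulated counts with this design, over 25028 genes, 9 unchanged genes were called. Of 100 genes changed by 4-fold 48 were called in the right direction, and of 100 changed by 16-fold 99. The changed genes were drawn only from genes with higher mean counts. Counts were drawn independently per gene, with the same dispersion in both groups. These numbers therefore do not cover low-count genes or genes that vary together.

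The test, the named-genes rule, 26 gene lists (23 of pathways and 3 of markers for other tissues) and the alternatives were fixed before the data were examined. The rule named OsMADS61 and OsMADS26, every tested nitrate transporter, and the 10 largest called rises and falls among genes with a name, at least 1 CPM on average and no overlap between groups. From each list it took up to 4 called members with the largest change or, where none was called, at most the 2 most abundant. Of 320 members, whose names and loci were written from memory, 276 were used, matched by locus or else by name. A further 21 were left out because name and locus led to different genes, the deposited symbol named another gene or the name led to several genes, and 23 loci were not analysed here. Each list was tested against other genes with camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, with adjustment over the 25 lists that had at least 3 tested members. Camera with an estimated correlation left 1 list past the threshold, nitrate reduction and ammonium assimilation (adjusted p = 0.038). In fry, which tests whether a list's genes move on balance one way, the adjusted p was 0.0456 for nitrate transporters, cytokinin response, phytoalexins and low-oxygen genes and 0.0241 for nitrate reduction, and the other lists did not pass. Fry's mixed test, which lets members move either way, did not pass for the ammonium transporter, iron storage, aquaporin, auxin and jasmonate lists. Nor did it for the cell cycle, secondary wall, photosynthesis, root hair and endodermis lists. It passed for the other lists tested, with adjusted p from 0.000301 (ethylene) to 0.0288 (potassium transporters).

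The alternatives were RLE or upper-quartile factors, no filter or a stricter filter (at least 1 CPM in 3 libraries and a mean count of 20), DESeq2 1.42.0, limma-voom, edgeR without robust estimation, the replicate number as a block, limma on log2(FPKM + 1) or log2(FPKM + 0.1), TREAT against a fold of 1.5, and leaving out each library. DESeq2 used its own scaling and filter, which left 28483 genes with an adjusted p, and its lists were tested on its Wald statistics. Limma on FPKM changed values, scaling and test together. Put in after seeing the data were the list members left out for contradicting names, a fit without the MSTRG features, and the gene families with each library left out and by the other tools. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.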

Results

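RNA was sequenced from 6 samples of rice (Oryza sativa) roots, 3 from wild-type (WT) plants and 3 from the mutant line mads61-3 of OsMADS61, a gene for a MADS-box transcription factor. The plants stood in a hydroponic medium with nitrate at 2.5 mM and without a fungal partner, and the comparison asked how OsMADS61 acts on nitrate transport in such roots. Total read counts were 26766480, 24145708 and 27338562 in WT replicates 1 to 3 and 34179150, 27060698 and 28250567 in mutant replicates 1 to 3. At these depths 3 counts stood for 0.0875 to 0.131 CPM (normalised read counts scaled to library size). Of 36960 features in the table, 25531 had enough counts to be tested. Between libraries of a group, Spearman's rho across genes, which are not independent replicates, was 0.9392, 0.8825 and 0.9514 in WT and 0.9646, 0.9856 and 0.9611 in the mutant, against 0.8932 to 0.9397 between groups. Every pair of libraries differed by more than sampling noise. The principal component with the largest share of variance (43.4%) parted WT (70.4 to 83.2) from mutant (-91.0 to -57.3), while the next (31.9%) spread the WT libraries from 122 to -103 and the mutants only from 21.9 to -29.4.

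**Figure D1:**
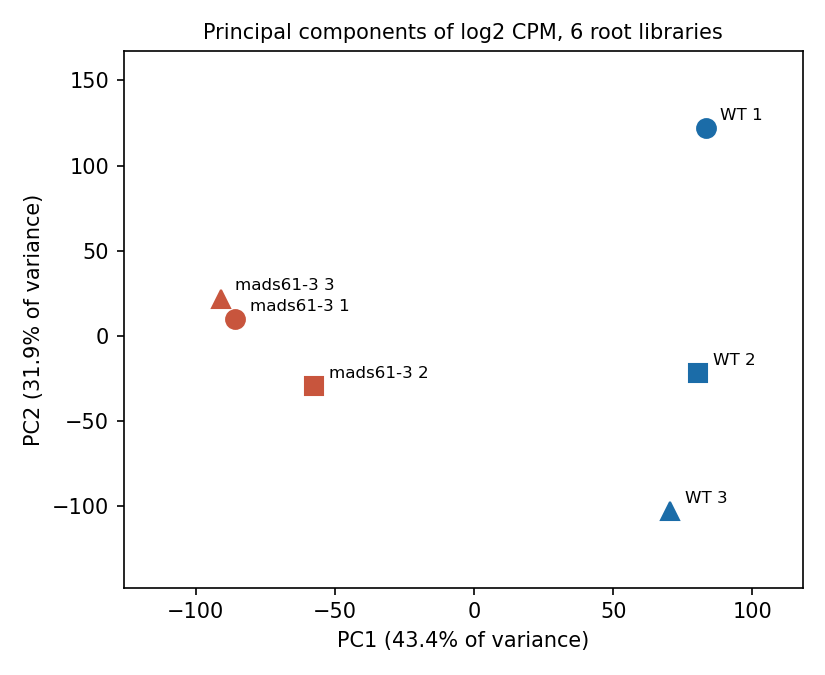
Principal components of log2 CPM for the 6 root libraries, with PC1 (43.4% of variance) on the horizontal and PC2 (31.9%) on the vertical axis, both in score units, and 1 point per library. The WT libraries lie between 70.4 and 83.2 and the mutants between -91.0 and -57.3 on PC1, and the WT libraries lie far apart on PC2, at 122, -21.8 and -103.

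OsMADS61 itself (Os04g0461300, chromosome 4) differed widely among the libraries labelled WT. Its read counts were 12600 and 14468 in WT replicates 1 and 2, but 67 in the library labelled WT replicate 3, against 214, 73 and 126 in the mutants. In CPM these were 552, 573 and 2.38 in the libraries labelled WT, and 6.24, 2.41 and 4.63 in the mutants, and the deposited FPKM were 243, 309 and 1.24 against 3.25, 1.38 and 2.3. The group means were 375.6 ± 323.4 CPM in WT and 4.425 ± 1.922 in the mutant (SD, n = 3 each), a log2 fold change of -6.40 (SE 1.71) that did not pass the test with that library included (edgeR, adjusted p = 0.129). Without the library labelled WT replicate 3 it was -6.99 (edgeR, adjusted p = 0.00746), and the range over all alternative settings was 0.00082 to 0.45. OsMADS26, the other regulator in the series title and listed as MADS26 (Os08g0112700, chromosome 8), had 66.0 ± 23.0 CPM in WT and 14.5 ± 10.2 in the mutant, with every mutant library below every library labelled WT. Its log2 fold change of -2.19 (SE 0.54) did not pass the test (edgeR, adjusted p = 0.11). In DESeq2 it did (log2 -2.18, adjusted p = 0.00179), with a range of 0.00179 to 0.344 over all alternative settings. All directions given from here on count the library labelled WT replicate 3 as WT, and WT replicates 1 and 2 too. Which libraries, if any, depart from their label is not settled here. A mutant allele need not lose its transcript, so OsMADS61 RNA alone cannot decide it. Members named below because they passed when adjusted over the list alone, or with 1 library left out, were chosen after their values were seen.

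Mutant roots had far fewer transcripts of the high-affinity nitrate transporters NRT2.1 and NRT2.2, of the nitrate reductase gene OsNIA1, of nitrite reductase (NiR) and of the haemoglobins HB1 and HB2 than WT roots. OsNIA1 fell from 97.5 ± 56.9 CPM to 0.0525 ± 0.0498, NRT2.1 from 20.2 ± 8.77 to 0.0608 ± 0.0758, and HB1 from 415 ± 219 to 1.42 ± 0.992 (mean ± SD, n = 3 per group, as for all CPM below). Rises among genes with a name included OsLOX10, a lipoxygenase gene, from 3.45 ± 1.81 to 52.7 ± 25.0 CPM, and OsPCL1, a clock gene, from 1.16 ± 0.543 to 12.6 ± 1.34. A locus without a name, Os03g0115800, picked after its values were seen, had 0 counts in every library labelled WT and 448 ± 173 CPM in the mutant, at least 3770-fold higher with 3 counts per library as the floor (adjusted p = 0.0146). In all, edgeR called 319 genes, 83 higher and 236 lower in the mutant, each by at least 2-fold, and 125 of them carried a gene name. The share called lower was 74%, against 61.1% when limma was run on log2(FPKM + 1) and 61.7% on log2(FPKM + 0.1), and DESeq2 called 2481 genes with 54.6% lower. The count hung on single libraries. It was 663 (228 higher, 435 lower) without WT replicate 1 and 107 (7 higher, 100 lower) without WT replicate 2. Without the library labelled WT replicate 3 it was 724 (195 higher, 529 lower), and without mutant replicate 2 it was 14 (9 higher, 5 lower). Without mutant replicate 1 or 3 edgeR called 0 genes, with 2641 and 2608 at an unadjusted p under 0.05 against 4222 in all libraries, and no other tool was run on those subsets. Of the 29 called genes picked by the rule fixed in advance, 0 stayed past the threshold when any 1 mutant library was left out. All 29 kept their sign, but this was fixed in advance. In each of them all mutant libraries lay on one side of all libraries labelled WT. In 5797 of the tested genes (22.7%) all mutant libraries lay on one side of all libraries labelled WT, where chance gives 10% on average over the splits. Genes vary together, so the share in a single split can lie far from 10%, and the shares of the other splits were not computed.

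In the nitrate transporters list, 2 of 19 tested members fell and 0 rose by edgeR, while 3 were higher and 5 lower at an unadjusted p under 0.05. DESeq2 called 1 higher and 4 lower, and limma-voom 0 and 3. NRT2.1 (Os02g0112100, chromosome 2) had a log2 fold change of -8.20 (SE 0.82, adjusted p = 0.0148). NRT2.2 (Os02g0112600, chromosome 2) went from 22.5 ± 10.2 to 0.11 ± 0.0969 CPM, with a log2 fold change of -7.63 (SE 0.82, adjusted p = 0.0176). The split of reads between NRT2.1 and NRT2.2, which are near-identical copies, is uncertain. NAR2.1, the partner protein of these transporters, had 100.2 ± 24.9 CPM in WT and 5.54 ± 4.38 in the mutant, a log2 fold change of -4.18 (SE 0.77) just outside the threshold (adjusted p = 0.0584). With p adjusted over the list alone, 4 members were lower (NRT2.1, NRT2.2, NAR2.1 and NRT1.1B, log2 -2.56) and 1 was higher (OsNRT1, log2 1.55), and without the library labelled WT replicate 3 these counts were 9 and 3. The other 14 tested members had log2 fold changes between -1.56 (OsNAR2.2) and 0.92 (Os01g0103100), among them NRT2.3 at -0.73, NRT2.4 at 0.06 and OsNRT1.1A at -0.38. The list's median was -0.72 and it was lower than other genes by camera (adjusted p = 0.000986), with adjusted p = 0.326 with an estimated correlation and adjusted p = 0.081 without WT replicate 1. The adjusted p of NRT2.1 was 0.0949, 0.0517 and 0.11 without mutant replicate 1, 2 and 3, that of NRT2.2 0.139, 0.0513 and 0.11, and without the library labelled WT replicate 3 both had 0.0122. Besides them 1 member was called higher without WT replicate 1 (OsPTR9, log2 1.20, adjusted p = 0.049) and 1 without the library labelled WT replicate 3 (OsNRT1, log2 2.18, adjusted p = 0.0122).

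**Figure D2:**
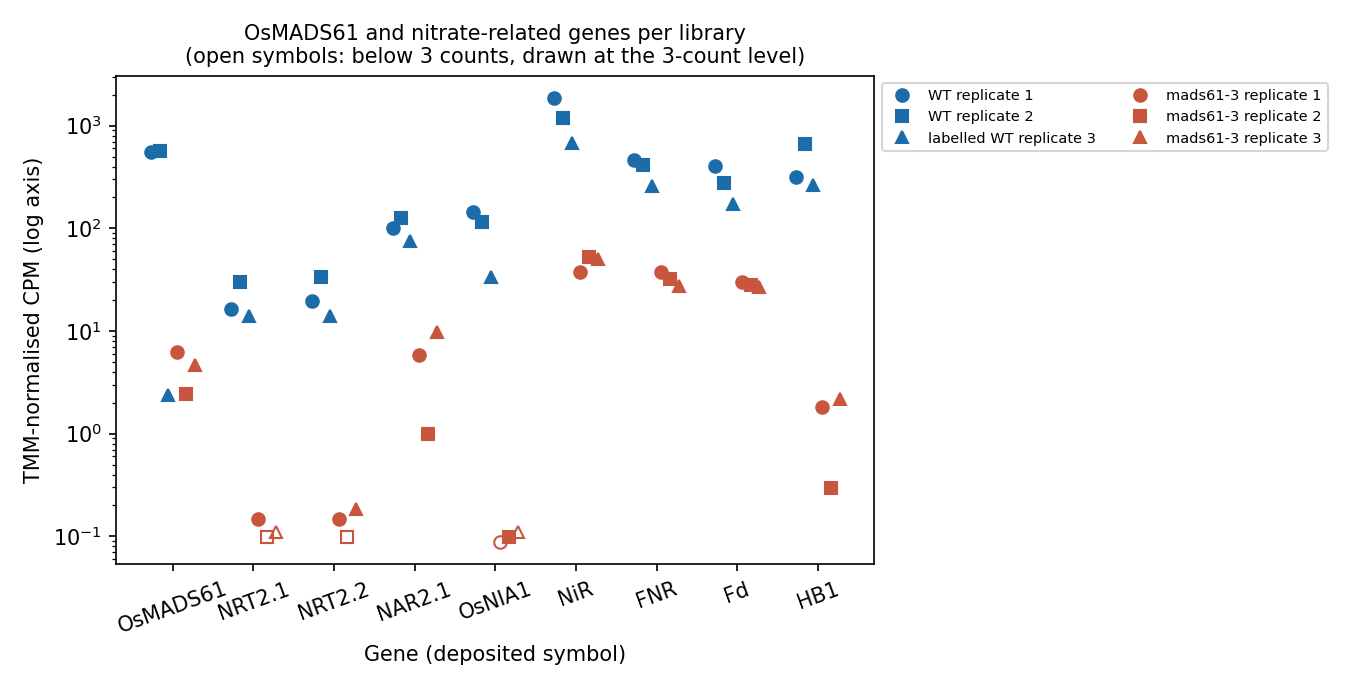
TMM-normalised CPM on a log axis for 9 genes in each of the 6 libraries, WT in blue and mads61-3 in red, with 1 symbol shape per replicate number and open symbols, drawn at the level of 3 counts, for values under it. OsMADS61 in the library labelled WT replicate 3 lies at 2.38 CPM, just below the mutants (2.41 to 6.24), whereas the other 8 genes in that library lie above all mutants.

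Genes of nitrate reduction and ammonium assimilation fell as a group. By edgeR 5 of 15 tested members fell and 0 rose, and adjusted over the list alone 9 were lower. At an unadjusted p under 0.05, 9 were lower, and DESeq2 called 9 lower and limma-voom 4, with 0 higher in each. OsNIA1 (Os02g0770800, chromosome 2) had a log2 fold change of -10.70 (SE 0.92, adjusted p = 0.0146), on a mutant total of 5 counts. In limma-voom it was not called (adjusted p = 0.0554). The list had written this locus as NR2, and NIA1 as a name of Os08g0468100, which the deposited table lists as OsNR1. NiR (Os01g0357100, chromosome 1), which turns nitrite into ammonium, went from 1244 ± 594.8 to 46.5 ± 7.82 CPM (log2 -4.74, SE 0.48, adjusted p = 0.0148). The genes for the proteins that bring electrons to nitrite reductase fell with it: FNR, a ferredoxin-NADP reductase, from 378 ± 109 to 32.4 ± 5.03 CPM (log2 -3.54, SE 0.32, adjusted p = 0.0146), and Fd, a ferredoxin, from 286 ± 117 to 28.3 ± 1.55 (log2 -3.34, SE 0.36, adjusted p = 0.0176). ASN1, an asparagine synthetase gene named here after its values were seen, went from 72.0 ± 7.04 to 17.1 ± 1.84 CPM (log2 -2.07, SE 0.20, adjusted p = 0.0146). The list's median was -1.58, with camera's adjusted p = 1.08e-16 and adjusted p = 0.038 with an estimated correlation. It held 8 called members without the library labelled WT replicate 3, adding OsNR1, OsNIA2 and OsGLT1, and 0 without any 1 mutant replicate, where OsNIA1, NiR, FNR and Fd had adjusted p between 0.0517 and 0.133. With the glutamine synthetase OsGLN2 put back, a choice made after seeing the data, 6 of 16 members fell, OsGLN2 by a log2 fold change of -3.17 (adjusted p = 0.0298).

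Ammonium transporters lay on the other side. All 5 tested members had positive log2 fold changes with a median of 0.65, and the AMT1;2 member (Os02g0620500, which the table lists as OsAMT1 without the paralog number) had 42.2 ± 17.9 CPM in WT and 227 ± 157 in the mutant (log2 2.43, SE 0.69, adjusted p = 0.149). In mutant replicate 2 the AMT1;2 member stood at 57.8 CPM, beside 55.6 in WT replicate 1, against 257 and 368 in mutant replicates 1 and 3. The AMT1;1 member (Os04g0509600, listed as AMT1) had a log2 fold change of 0.05 (adjusted p = 0.956). No single member was called by edgeR, all genes or adjusted over the list alone, with 3 higher at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Camera gave the list a higher level (adjusted p = 0.0252), with adjusted p = 0.557 with an estimated correlation. That call was lost without WT replicate 1 (adjusted p = 0.081), mutant replicate 1 (0.071) and mutant replicate 3 (0.0551).

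Among nitrate signalling genes and MADS genes of the ANR1 clade, 1 of 12 tested members fell and 0 rose. It was OsBT (Os01g0908200, chromosome 1), a BTB-domain gene of the nitrate response, at 62.7 ± 19.3 CPM in WT and 9.65 ± 2.43 in the mutant (log2 -2.70, SE 0.32, adjusted p = 0.0215). When adjusted over the list alone, OsBT, OsMADS61, NIGT1 (log2 -2.13) and OsMADS57 (log2 -1.67) were lower and OsMADS27 (log2 0.80) was higher. The list's median was -0.33 and camera did not call it (adjusted p = 0.0601), but without the library labelled WT replicate 3 it did (adjusted p = 2.69e-05), with OsBT, OsMADS61 and OsMADS57 lower. It also did without mutant replicate 1 (0.0396) or 3 (0.0268), without a filter on low counts (0.0324) and in DESeq2 (0.0337). OsMADS61 is itself a member, so leaving out the library labelled WT replicate 3, set apart by its low OsMADS61, lowers the list partly by construction. The call of OsBT was lost without WT replicate 2 (adjusted p = 0.0581) and without mutant replicate 1, 2 or 3 (0.106, 0.0751 and 0.146).

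Both haemoglobin genes of the low-oxygen and fermentation list fell. HB1 (Os03g0233900, chromosome 3) had a log2 fold change of -8.18 (SE 0.88, adjusted p = 0.0176) and HB2 (Os03g0226200, chromosome 3), from 452 ± 181 to 9.24 ± 5.90 CPM, one of -5.61 (SE 0.76, adjusted p = 0.0302). Plant haemoglobins of this kind scavenge nitric oxide, and the split of reads between these similar copies is uncertain. They were the 2 called of 8 tested members, with 0 higher, and adjusted over the list alone 4 were lower, the others being the fermentation genes ADH1 (log2 -1.96) and PDC2 (log2 -1.14). Of the 8, 6 had negative and 2 had positive log2 fold changes. With a median of -1.21 the list was lower by camera (adjusted p = 1.87e-06), with adjusted p = 0.326 with an estimated correlation. It had 4 called members without the library labelled WT replicate 3 (also ADH1 and PDC2), 3 without WT replicate 1 (also ADH1) and 1 without WT replicate 2, where HB2 had adjusted p = 0.0691. Without mutant replicate 1, 2 or 3 the adjusted p was 0.138, 0.0513 and 0.11 for HB1 and 0.16, 0.0517 and 0.152 for HB2.

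Of 12 iron deficiency genes tested, 1 fell and 0 rose. It was the gene at Os01g0647200 (chromosome 1), listed as IMA1, an iron-signalling peptide gene. Its mutant libraries held 2 counts in all, against 41, 303 and 98 in the libraries labelled WT replicates 1 to 3, a ratio of the depth-scaled totals of 266 (95% counting interval 73.3 to 2210, adjusted p = 0.0416). When adjusted over the list alone 6 members were lower, among them OsIRO2 (log2 -2.42) and OsIRO3 (log2 -2.02), transcription factors of the iron response, and NRAMP1 (log2 -2.47). The median was -0.93, with camera's adjusted p = 0.00417, adjusted p = 0.557 with an estimated correlation, and adjusted p = 0.063 without WT replicate 1. Without the library labelled WT replicate 3, 4 members were called lower, adding OsIRO2, OsIRO3 and NRAMP1, and without WT replicate 2 the gene at Os01g0647200 was not (adjusted p = 0.0759), nor without mutant replicate 1, 2 or 3 (0.203, 0.114 and 0.198). Of 3 iron storage genes edgeR called 0, and 0 also adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 and by limma-voom. The ferritin gene OsFER1 stood at 28.0 ± 11.9 and 25.1 ± 5.89 CPM, and the list's median was 0.23 (camera, adjusted p = 0.541).

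All 6 potassium transporter genes had positive log2 fold changes, with a median of 1.65. HAK1 had 50.4 ± 4.71 CPM in WT and 183 ± 115 in the mutant (log2 1.86, SE 0.58, adjusted p = 0.177) and OsAKT1 had 55.0 ± 4.65 and 155 ± 119 (log2 1.49, SE 0.59, adjusted p = 0.276). By edgeR 0 were called and adjusted over the list alone 2 were higher (HAK5, log2 2.71, and HAK1), with 4 higher at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. Camera called the list higher (adjusted p = 0.00235), with adjusted p = 0.348 with an estimated correlation and adjusted p = 0.056 without WT replicate 1. In mutant replicate 2 HAK1 stood at 49.4 CPM, within the WT range of 45.0 to 53.9. For 8 aquaporins and silicon transporters edgeR called 0, also adjusted over the list alone, with 2 higher at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. The silicon transporters LSI1 (1002 ± 556 and 2746 ± 1034 CPM, log2 1.45, adjusted p = 0.24) and LSI2 (765.5 ± 598 and 2488 ± 1068, log2 1.70, adjusted p = 0.264) were its most abundant members, and the list's median was -0.55 (camera, adjusted p = 0.856).

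Genes for the diterpenoid phytoalexins, antimicrobial compounds of rice, stood higher in the mutant. NOMT, the list's gene for a flavonoid phytoalexin, had 0 counts in every library and was not tested. All 12 tested members had positive log2 fold changes with a median of 2.66, and the list was higher by camera (adjusted p = 1.27e-09), with adjusted p = 0.326 with an estimated correlation. By edgeR 1 rose and 0 fell, CYP99A3 (Os04g0178400, chromosome 4) of momilactone synthesis, from 1.36 ± 0.815 to 17.5 ± 8.59 CPM (log2 3.68, SE 0.59, adjusted p = 0.0416). The count adjusted over the list alone was 8 higher, among them OsCPS4 (log2 3.24), OsKS4 (log2 2.53) and OsMAS (log2 2.63) of the same pathway and DPF (log2 2.1), a transcription factor for diterpenoid synthesis. The call of CYP99A3 was lost without any 1 library, with adjusted p of 0.0536, 0.0583 and 0.0525 without WT replicate 1, 2 and the library labelled WT replicate 3 and of 0.183, 0.0642 and 0.177 without mutant replicate 1, 2 and 3. Without WT replicate 1, the list's called members were OsCPS4 (adjusted p = 0.0496) and CYP99A2 (adjusted p = 0.0309). Of 11 pathogenesis-related and defence genes edgeR called 0, with 2 higher and 1 lower at an unadjusted p under 0.05 and likewise by DESeq2, 0 by limma-voom, and WRKY45 (log2 -1.56) lower adjusted over the list alone. That list's median was -0.18, its mean 0.20 and camera's direction up (adjusted p = 0.856). Its most abundant members were JIOsPR10 (92.4 ± 62.1 and 184 ± 82.5 CPM, adjusted p = 0.49) and WRKY13 (80.3 ± 24.6 and 59.3 ± 6.67 CPM, adjusted p = 0.466). Without the library labelled WT replicate 3, RSOsPR10 was called higher (log2 2.22, adjusted p = 0.027).

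In the arbuscular mycorrhizal symbiosis list, 1 of 14 tested members rose and 0 fell. DMI3 (Os05g0489900, chromosome 5), the calcium- and calmodulin-dependent kinase of the common symbiosis pathway, went from 6.93 ± 0.671 to 23.7 ± 6.68 CPM (log2 1.77, SE 0.28, adjusted p = 0.0416). Once adjusted over the list alone, DMI3, its partner IPD3 (log2 1.74) and the transcription factor NSP1 (log2 2.99) were higher and MADS26 was lower, and the median of all members was 0.03 (camera, adjusted p = 0.181). DMI3 was not called without WT replicate 2 (adjusted p = 0.126), the library labelled WT replicate 3 (0.0505) or mutant replicate 1, 2 or 3 (0.182, 0.0606 and 0.191). Among 12 genes of phosphate transport and phosphate starvation, 1 rose and 0 fell: the phosphate transporter PT4 (Os04g0186400, chromosome 4), from 0.706 ± 0.282 to 4.95 ± 1.33 CPM (log2 2.81, SE 0.46, adjusted p = 0.0429). Those higher when adjusted over the list alone were PT4 and PT2 (log2 2.81), and the list's median was 0.09 (camera, adjusted p = 0.673). The call of PT4 was lost without WT replicate 1 (adjusted p = 0.0531), WT replicate 2 (0.085) and mutant replicate 1, 2 or 3 (0.197, 0.0828 and 0.196). PT2 was called higher without mutant replicate 2 (adjusted p = 0.0448), and PT6 lower without the library labelled WT replicate 3 (log2 -3.13, adjusted p = 0.0319). Of 10 strigolactone genes edgeR called 0, with 1 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and 0 by limma-voom. With p adjusted over the list alone D10 (log2 2.05), a carotenoid-cleaving enzyme of strigolactone synthesis, was higher, with D14, the hormone's receptor, at 130.3 ± 45.6 and 77.3 ± 6.94 CPM (adjusted p = 0.274) and D53, a repressor of its signalling, at 91.8 ± 45.2 and 50.6 ± 10.7 CPM (adjusted p = 0.36). The list's median was -0.47 (camera, adjusted p = 0.856).

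Of the hormone lists, abscisic acid held the only called gene. OsABA8OX1 (Os02g0703600, chromosome 2), which breaks down abscisic acid, fell from 222 ± 148 to 19.2 ± 2.4 CPM (log2 -3.53, SE 0.49, adjusted p = 0.0316), 1 of 9 tested members, with 0 higher, 1 lower adjusted over the list alone and a median of -0.34 (camera, adjusted p = 0.541). WT replicate 1 had 392 CPM of OsABA8OX1, against 139 and 135 in the other libraries labelled WT, and without WT replicate 1 the log2 fold change was -2.83. OsABA8OX1 was not called without WT replicate 2 (adjusted p = 0.0537) or mutant replicate 1, 2 or 3 (0.169, 0.103 and 0.172), and without the library labelled WT replicate 3 BZIP46 was also called, higher (log2 3.85, adjusted p = 0.0255). Cytokinin response genes were lower by camera (9 tested, median -0.57, adjusted p = 0.0215), with adjusted p = 0.348 with an estimated correlation, 0.062 without WT replicate 1 and 0.0791 without WT replicate 2. In that list edgeR called 0, with 4 lower at an unadjusted p under 0.05, and limma-voom called 0. OsCKX5 (log2 -1.56), which degrades cytokinins, was lower adjusted over the list alone (4 lower without the library labelled WT replicate 3). DESeq2, with its own filter, called 1 higher and 1 lower among the members it kept. The higher one lay outside the 9, of which RR4 alone had a positive log2 fold change. CKX2, also outside the 9, had 5, 3 and 31 counts in mutant replicates 1 to 3 and 0 in each library labelled WT. The response regulators RR4 and OSRR2 had log2 fold changes of 0.01 and -0.75. In the auxin (8 tested, median -0.50, camera adjusted p = 0.541), jasmonate (6, median -0.42, 0.458) and ethylene (7, median -0.47, 0.293) lists edgeR called 0 genes. At an unadjusted p under 0.05 these had 1 lower, 2 lower, and 1 higher with 2 lower, DESeq2 called 0, 1 lower, and 1 higher with 2 lower, and limma-voom called 0 in each. The counts adjusted over the list alone were 0 for auxin and jasmonate, and ethylene had ACO1 (log2 1.34) higher and ACO3 (log2 -1.68) and ACS1 (log2 -2.71), enzymes of ethylene synthesis too, lower. The auxin carriers OsLAX1 and OsPIN2 had log2 fold changes of -0.59 and -1.44, the jasmonate genes AOC and OsbHLH009 -0.88 and -0.86, and the ethylene genes EIL1 and ETR2 -0.20 and -0.47. Without WT replicate 1, OsPIN2 was called lower (adjusted p = 0.0499), and without WT replicate 2 camera called the jasmonate list lower (median -0.64, adjusted p = 0.039). The 5 JAZ repressors had been left out of the jasmonate list because their names and deposited symbols did not match, and with them kept, after seeing the data, 2 of 11 fell, TIFY11A (log2 -6.64, adjusted p = 0.0195) and OsJAZ4 (log2 -3.71, adjusted p = 0.0313), with a median of -0.88 (camera, adjusted p = 4.4e-05).

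Among genes with a name and at least 1 CPM on average, the 10 largest called rises were OsCFR (log2 4.93), OsDXS (4.48), Os4bglu16 (4.28), OsLOX10 (3.93), OsPCL1 (3.43), the gene the table names LHY at Os04g0583900 (2.93), PT4 (2.81), OsHAP2K (2.70), OsDjC45 (2.69) and ICS1 (2.63). OsDXS, the entry enzyme of plastid isoprenoid synthesis, went from 1.16 ± 0.548 to 26 ± 17.3 CPM (SE 0.63, adjusted p = 0.0318). ICS1, of the isochorismate branch of salicylate synthesis, went from 4.76 ± 0.334 to 29.5 ± 8.42 CPM (SE 0.29, adjusted p = 0.0176). Their adjusted p lay between 0.0176 and 0.0489 in all libraries, 0 of the 10 stayed called without WT replicate 2 (0.0518 for OsPCL1 to 0.141 for OsDjC45), and OsHAP2K (0.0639) and OsDjC45 (0.0589) were not called without the library labelled WT replicate 3. PT4 was not called without WT replicate 1 (0.0531), and without mutant replicate 1, 2 or 3 the rises had adjusted p from 0.0513 to 0.198. Fitted values of genes with a handful of counts depend on the prior count of the fit. Under the same limits the 10 largest called falls were DERF3, OsNIA1, Os11gRGA5 (log2 -10.36), OsATL15, SIP28 (-9.05), NRT2.1, HB1, OsDREB1B (-8.03), OsERF_133 and NRT2.2. DERF3, an ethylene response factor gene, had 0 counts in the mutant and 18.4 ± 12.2 CPM in WT, and so was at least 186-fold lower, with 3 counts per library as the floor (adjusted p = 0.0417). OsATL15 and OsERF_133 had 2 mutant counts each, with ratios of 1070 (95% counting interval 294 to 8800) and 233 (64.0 to 1930). Os11gRGA5, a resistance gene on chromosome 11, had 62.3 ± 28.8 CPM in WT and 0.0402 ± 0.0442 in the mutant (SE 0.73, adjusted p = 0.0123), and SIP28 47.3 ± 6.65 and 0.0778 ± 0.135 (SE 0.91, adjusted p = 0.0148). Loci without a name were outside these limits, among them Os11g0226700, picked after its values were seen, which had 22.8 ± 12.3 CPM in WT and 0 counts in the mutant, at least 230-fold lower (adjusted p = 0.0215). Of the 10 falls OsERF_133 alone was not called without WT replicate 2 (0.0578). Without mutant replicate 1, 2 or 3 these falls had adjusted p from 0.0513 to 0.183.

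Among markers of shoot tissue, all 21 photosynthesis genes tested had positive log2 fold changes, with a median of 3.30, and the list was higher by camera (adjusted p = 7.01e-12), with adjusted p = 0.449 with an estimated correlation. By edgeR 0 were called, with 15 higher at an unadjusted p under 0.05, 10 by DESeq2 and 0 by limma-voom, and adjusted over the list alone 13 were higher, but 0 without the library labelled WT replicate 3. The Rubisco small subunit genes RBCS (Os12g0274700) and RbcS3 (Os12g0291100), copies that may share reads, had 2.31 ± 2.11 and 0.928 ± 1.5 CPM in WT and 33.9 ± 31.0 and 31.1 ± 31.5 in the mutant (adjusted p = 0.147 and 0.184). The median of the members' centred log2 CPM was -2.41, -0.21 and -2.29 in the libraries labelled WT replicates 1 to 3 and -0.06, 2.78 and 2.23 in the mutants, so that mutant replicate 1 lay beside WT replicate 2. Without WT replicate 1, OsPrk, the phosphoribulokinase gene, was called higher (log2 4.55, adjusted p = 0.0407).

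Growth and tissue markers were tested in the same way. Of 12 cell cycle and DNA replication genes edgeR called 0, and 0 adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 or by limma-voom. All 12 had negative log2 fold changes (median -0.33, camera adjusted p = 0.561), with OsPCNA at 89.9 ± 42.0 and 54.4 ± 9.60 CPM and CycB1 at 85.1 ± 60.9 and 63.4 ± 25.0, and the library medians were -1.28 in WT replicate 1, 0.60 in WT replicate 2 and 0.72 in the library labelled WT replicate 3. Without the latter the list's median was 0.04, and without WT replicate 1 it was -0.78 and the list was lower by camera (adjusted p = 0.000178). Secondary wall and lignin genes, 9 tested, had a median of 0.61 and were higher by camera (adjusted p = 0.0278), with adjusted p = 0.67 with an estimated correlation, 0.0966 in DESeq2, 0.329 without WT replicate 1, 0.118 without WT replicate 2 and 0.071 without mutant replicate 1. In that list edgeR called 0 and 0 adjusted over the list alone, with 1 higher at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom, and ROMT9 stood at 199 ± 111 and 399.7 ± 128 CPM and 4CL3 at 166 ± 50.7 and 238 ± 51.8. Without the library labelled WT replicate 3 the median was 1.57 (camera, adjusted p = 8.47e-10), with 7 members higher adjusted over the list alone. Called higher there were the cellulose synthases OsCesA4, CESA7 and BC6 (the list's CESA9) and the brittle culm gene BC1. Of 3 root hair and 6 endodermis, ground tissue and quiescent centre genes edgeR called 0, and 0 also adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 and by limma-voom. Their medians were -0.09 and -0.30 (camera, adjusted p = 0.856 and 0.556), with OsFH1 at 47.8 ± 27.9 and 44.8 ± 6.58 CPM and OsSHR1 at 19.4 ± 7.25 and 21.4 ± 4.03.

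In the circadian clock list, 1 of 10 tested members rose and 0 fell. It was OsPCL1 (Os01g0971800, chromosome 1), the LUX gene of the evening complex (log2 3.43, SE 0.41, adjusted p = 0.022), and adjusted over the list alone OsPCL1 was higher and CCA1 (Os08g0157600, log2 -1.81), a morning-phased regulator, lower. The list's median was -0.09 and its mean -0.04, while camera's direction was up (adjusted p = 0.956). OsPCL1 was not called without WT replicate 2 (adjusted p = 0.0518) or mutant replicate 1, 2 or 3 (0.144, 0.0588 and 0.133). Of the heat shock list 2 members had enough counts, so no set test was run, and edgeR called 0, with 1 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. HSfA2a (5.87 ± 5.47 and 0.174 ± 0.154 CPM, log2 -5.0, adjusted p = 0.0969) was lower adjusted over the list alone, and HSP101 had a log2 fold change of 0.89 (adjusted p = 0.456).

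**Figure D3:**
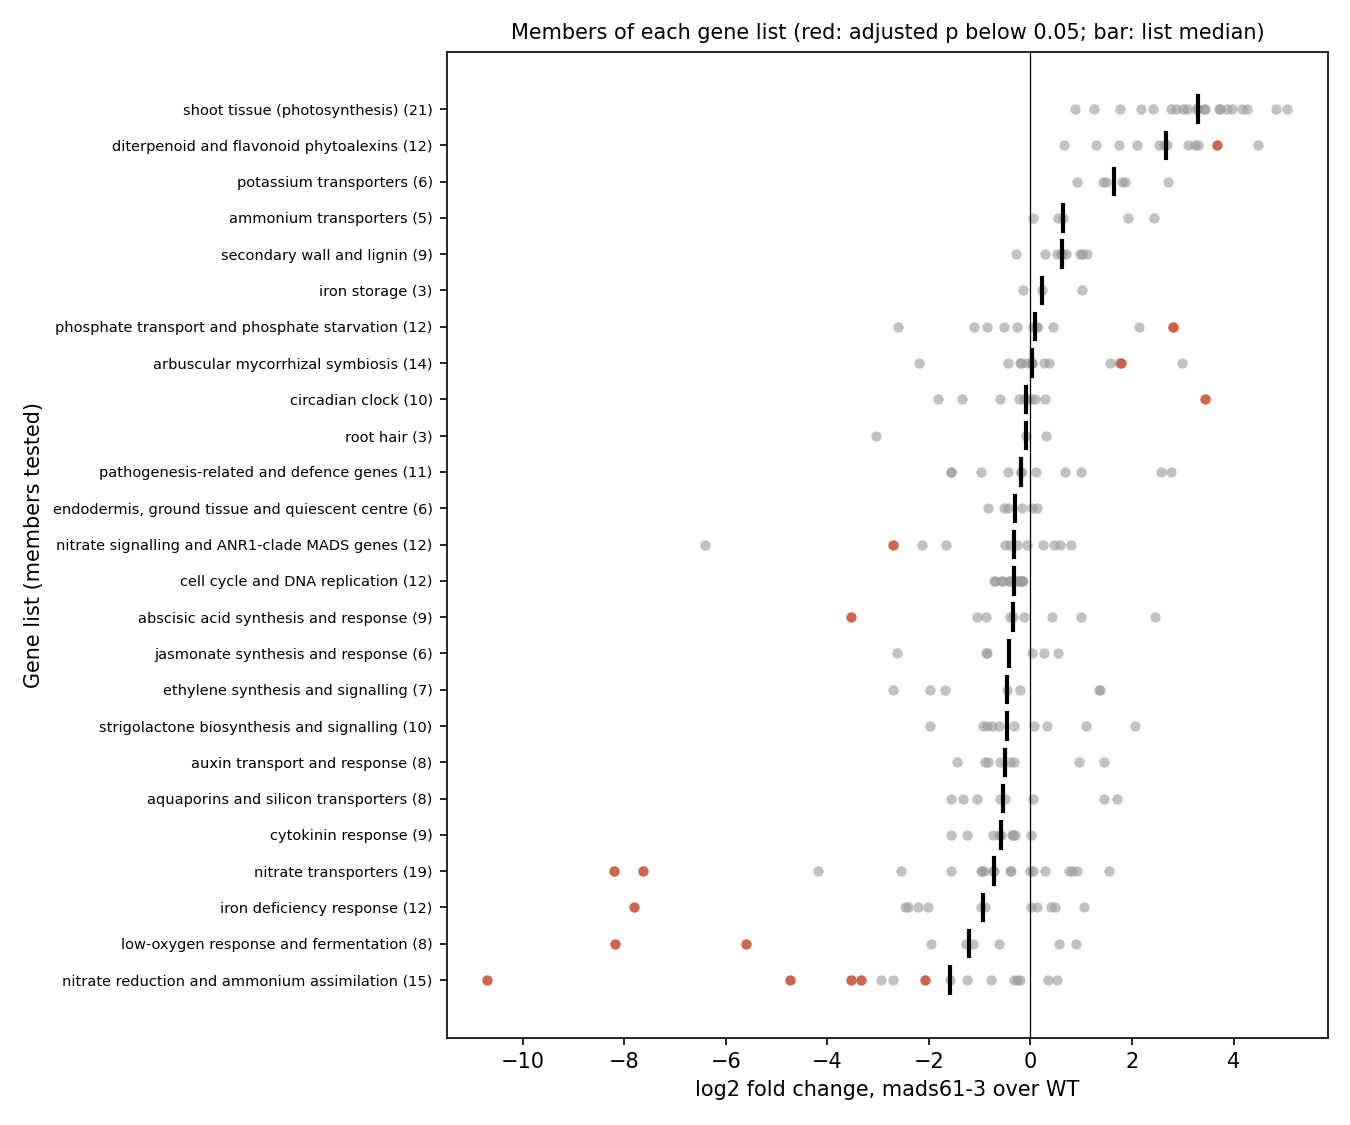
Log2 fold changes, mads61-3 over WT (horizontal axis), of the tested members of 25 gene lists (vertical axis, members tested in brackets), with members past adjusted p 0.05 in red, others in grey and a bar at each list's median. Medians run from -1.58 for nitrate reduction and ammonium assimilation to 3.30 for photosynthesis genes, and the called members include NRT2.1 and OsNIA1 among the falls and CYP99A3 and OsPCL1 among the rises.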

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

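Among the alternatives in this part only the contradicting list members put back and the fit without MSTRG features (83 higher, 233 lower) were chosen after the data were seen. All 319 called genes kept their sign wherever they were tested, but every fit used the same libraries or all but 1 of them. RLE factors (324 genes), no filter (311), the stricter filter (346) and edgeR without robust estimation (385) gave counts within 1.5 times the main one. Upper-quartile factors gave 125 higher, also at a fold of 2 (125). DESeq2 called 1127 higher and 1354 lower (1002 and 1209 at a fold of 2), all 319 among them, and limma-voom 226 in all. Genes picked by the rule that DESeq2 called and edgeR did not were OsMADS61, MADS26, NAR2.1, NRT1.1B, OsNRT1, OsAMT1, HAK1, LSI1, LSI2, HSfA2a and RBCS, and the cause was not tested. Limma on log2(FPKM + 1) gave 187 higher (171 at a fold of 2) and on log2(FPKM + 0.1) 214 higher (213). TREAT against a fold of 1.5 left 29 higher and 144 lower, the same at a fold of 2, by its stricter null. With 1 library left out the calls ranged from 0 to 228 higher and from 0 to 529 lower, at a fold of 2 likewise, the zeros coming without mutant replicate 1 or 3 and the highest without WT replicate 1 (higher) and without the library labelled WT replicate 3 (lower). Fewer samples lower the power of such fits, but why leaving out WT libraries raised or lowered the count was not tested.

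OsMADS61 passed the threshold in DESeq2 (-6.39, adjusted p = 0.00082) and without the library labelled WT replicate 3 (-6.99, adjusted p = 0.00746), with a range from -6.99 to -5.96 over the left-out libraries and of adjusted p from 0.00082 to 0.45 over all alternatives. For the nitrate transporters list, DESeq2 called 1 member higher and 4 lower, and with 1 library left out 0 to 1 were higher and 0 to 2 lower. Its median ran from -0.82 to -0.53, with camera's adjusted p = 0.081 without WT replicate 1 and adjusted p = 0.326 with an estimated correlation (median -0.72). Apart from the constructions named, the cause of these differences was not tested.

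With the replicate number as a block, 18 genes were higher and 63 lower (the same at a fold of 2), 73 of them shared with the main calls, and 1 nitrate transporter was lower. Whether the numbers pair the samples could not be settled. Same-numbered libraries deviated from their group means with r = 0.112, 0.193 and -0.177, and not every sample correlated best with its own number. With 3 libraries per group such values cannot exclude a shared batch. Of 29 called genes picked by the rule fixed in advance, 29 stayed called with RLE or upper-quartile factors, the stricter filter, DESeq2, edgeR without robust estimation and log2(FPKM + 0.1), 28 without a filter, 25 with log2(FPKM + 1), 17 with limma-voom, 10 with the block, and 27, 12 and 25 without WT replicate 1, WT replicate 2 and the library labelled WT replicate 3. Depth limited values under 3 counts, 0.0875 to 0.131 CPM.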

Other observations

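All tests in this part were chosen after the results were seen, and so were the gene families, the genes named from them and the thresholds of 3 and 30 counts for genes on in 1 group and off in the other. Several families of stress-related genes had members among the called falls. Of 7399 tested genes with a name, 102 were lower and 23 higher, and 22 families picked by name were compared with the rest by Fisher's exact test with Benjamini-Hochberg adjustment. AP2/ERF transcription factors, which act in ethylene and stress responses, held 11 falls among 85 genes and 0 rises (adjusted p = 3.98e-07), among them OsDREB1B, OsDREB1C (log2 -7.01) and ERF77 (log2 -3.40, from 101 to 9.54 CPM). In 8 of the 11 WT replicate 1 was the highest library, as in OsDREB1B (91.1 CPM, against 14.2 in WT replicate 2 and 20.1 in the library labelled WT replicate 3) and ERF91 (86, 22.1 and 36.6 CPM). Without WT replicate 1 the family still had 12 falls (adjusted p = 4.18e-05), without WT replicate 2 it had 5 (0.00865) and without the library labelled WT replicate 3 it had 15 (1.33e-06), while limma-voom called 3 (0.172) and DESeq2 26 (2.85e-07).

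In other families the outcome changed with the library left out or with the tool. Calmodulin-like genes had 4 falls among 24 (adjusted p = 0.00284), such as OsCML16 (log2 -4.41), 3 of the 4 highest in WT replicate 1, and passed in DESeq2 (6.69e-05), in limma-voom (0.00195) and without the library labelled WT replicate 3 (0.000756) but not without WT replicate 1 (0.0735) or 2 (0.551). NAC genes had 3 falls among 15 (adjusted p = 0.00564), such as SNAC1 (from 139 to 17.3 CPM), and stress-associated zinc finger genes 3 among 11 (adjusted p = 0.00284), such as SAP11 (log2 -2.72), all of them highest in WT replicate 1. Neither passed without WT replicate 2 (0.514 for NAC, 1 for zinc finger genes), nor did the zinc finger genes in DESeq2 (0.119). Both passed in limma-voom (0.00459 and 0.0385), without WT replicate 1 (0.00423 and 0.0151) and without the library labelled WT replicate 3 (0.0051 and 0.0176), and NAC genes in DESeq2 (0.0159). VQ genes had 3 falls among 22 (adjusted p = 0.0142; 0.0695 without WT replicate 1, 1 without WT replicate 2 and 0.553 in limma-voom, but 0.00422 without the library labelled WT replicate 3 and 0.046 in DESeq2). EXO70 genes, of the exocyst, had 3 among 32 (adjusted p = 0.0346), all highest in WT replicate 1, and passed without WT replicate 2 (0.0163) but not without WT replicate 1 (0.117). Nor did they pass without the library labelled WT replicate 3 (0.183), in DESeq2 (0.177) or in limma-voom (0.172). WRKY genes, with 4 among 81, did not pass (adjusted p = 0.0793) but did without WT replicate 2 (0.00132) and in DESeq2 (6.69e-05). Other families that passed in DESeq2 and not in edgeR were heat shock genes with 8 falls among 45 (0.046), photosynthesis genes with 11 rises among 26 (1.83e-07) and ABCG and PDR transporters with 7 rises among 41 (0.0289). HAP2 genes, which encode NF-Y subunits, had 2 rises among 11 (adjusted p = 0.011), OsHAP2K and OsHAP2J (log2 1.82). They passed in no fit without a WT library (0.0865 without WT replicate 1, 0 rises without WT replicate 2, 0.909 without the library labelled WT replicate 3), nor in DESeq2 (0.0929) or limma-voom (0.334).

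Genes are not independent replicates, and family members may be regulated together, so these p-values describe groups of names and not samples. In edgeR 0 genes of these families were called without mutant replicate 1, 2 or 3, where all calls numbered 0, 14 and 0, with 2641, 3935 and 2608 genes at an unadjusted p under 0.05, and no other tool was run on those subsets. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 319 calls in edgeR. The highest other gave 0, and 10 splits are too few for a share under 0.05. Each other split also mixes WT and mutant libraries on both sides. A group difference then adds to the spread within sides and lowers the calls, so the 0 does not strengthen the real split.

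In the library labelled WT replicate 3, OsMADS61 had 67 counts, fewer than in any mutant (73 to 214), whereas WT replicates 1 and 2 had 12600 and 14468. A wrong label on mutant roots is argued against by the 52 genes on in WT replicates 1 and 2 and off in the mutants or the reverse, of which this library stood on the mutant side in 13.5% (7 genes, with 32 on the WT side and 13 between). Mutant RNA mixed into the library is argued against by Os03g0115800, with 0 counts in every library labelled WT and 448 ± 173 CPM in the mutants, which limits the share to 0.0238%. Colonisation of WT replicates 1 and 2 by a mycorrhizal fungus is argued against by PT11, the phosphate transporter of colonised cells, which had 0 counts in both, although mutant replicate 3 had 19. It stays open whether WT replicates 1 and 2 came from plants with raised OsMADS61, such as the overexpressing plants the growth protocol mentions, or whether this library came from other roots with low OsMADS61, and neither was tested.

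The low nitrate genes of the mutants may follow OsMADS61 RNA or something else that differed between the groups. Placed on a scale from the mutants (0) to WT replicates 1 and 2 (1), the library labelled WT replicate 3 had a median place of 0.782 over the 10 nitrate genes called lower without it (0.388 to 1.1, 8 of 10 closer to WT), against 0.638 over all 724 genes called without it. OsMADS61 RNA level alone predicts a place near 0, but 1 library with low OsMADS61 cannot decide this. A lower nitrate supply to the mutant tanks predicts most members of the nitrate reduction list lower, and 13 of 15 were, which the groups cannot tell apart from an effect of the mutation. Both explanations stay open, the mutation itself included.

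Of 22 loci off (3 counts or fewer in every library) in 1 group and on (30 or more) in the other, 14 were off in the mutant and 8 in the libraries labelled WT. A variant between the seed stocks in linked loci predicts that such loci lie together, and 4 of the 22 had another within 10 loci. Random draws of as many of 21202 expressed loci had a median of 0 (permutation p = 0.0068), and of the 286 other called loci also 0 (permutation p = 0.0159), each over 10000 draws. All 4 form 1 cluster on chromosome 11 (Os11gRGA5, Os11g0226400, Os11g0226550 and Os11g0226700), from which the test was conceived, so whether a linked variant accounts for it stays open. An effect of the mutation itself on these loci stays open too and was not tested.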
